A study of Mus musculus with 30 samples.

How the data were processed

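CUT&Tag libraries were made from sorted primary microglia of adult C57BL/6J mice, per the labels' protocols, after tamoxifen on 7 consecutive days. The 30 samples form 10 groups of 3 replicates (2 genotypes by 5 antibodies), taken from the sample titles. The series text mentions 4 mice beside 3 replicates per genotype, and the labels do not say whether replicates came from separate mice. The series names the assay as ChIP-seq, while the labels' protocol describes CUT&Tag. The protocol gives the same catalogue number for the H3K27ac, Pol II and Pol II Ser5P antibodies, and another shared by H3K4me3 and Pu.1.

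The files analysed are 10 lists of regions, 1 per antibody and genotype, without values per replicate. Bowtie2 2.4.4, MACS2 2.2.7.1, bedtools 2.30.0 and HOMER 4.11 are named, with the builds GRCm38 and mm10, per the submitters' processing notes. What each tool did, how replicates were combined and how a region became genotype-specific are not given in the sources used here. Each line of the deposited lists holds a region's position, a name with the word primary or secondary and a number, a score, a signal, a p-value and an adjusted p-value (q-value). The deposited score runs from 1 to 1000. The deposited signal is the authors' value per region on an unstated scale, and it was not compared between lists. The deposited p-value has a median between 0.724 and 0.862 across lists. What it tests is not given in the sources used here. It was used to rank or filter regions within each list, and the filtered lists were compared by count. The same cutoff may not mean the same in every list. Of the names, 907 hold the word primary and 21492 secondary. Depth and read counts are unknown, so intervals cover the counting of regions only. Names are numbered in genome order from 0. The highest number in a list plus 1 was taken as the least number of regions numbered before selection.

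Positions are given on mm10, counted from 1. Genes came from a RefSeq table of the same assembly with 49943 genes on placed chromosomes, of which 21887 are protein-coding. It gives the 2 ends of each gene but no strand, exon or transcript start. The plan used transcription start sites, so either gene end stood in for them: a region was assigned to the protein-coding gene whose end lay nearest its midpoint, within 100 kb, and a gene-end region overlapped 2 kb on either side of an end. This counts some regions at 3' ends. Assignment succeeded for 94.6% of regions, and 1212 stayed unassigned. Exons, introns and UTRs were not annotated. No genome sequence was used here, so the searches for the Pu.1 motif and the miR-137 seed were not run.

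The tests, gene lists and rule for named genes were fixed before the data were examined, except for the use of gene ends and what is said below or in the closing section to be added. The cKO share of each antibody has an exact Clopper-Pearson interval of 95%. Gene-end and chromosome X shares were compared by two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over the 5 antibodies, and mean log2 widths by a two-sided permutation test with 100000 resamples. A gene counted as cKO or cWT for an antibody where its regions lay in 1 list only. For each of 10 pairs of antibodies, these directions were compared by Fisher's exact test. For each of 20 fixed gene lists and each antibody with at least 5 such members, list members were compared with all other such genes. Odds ratios and their intervals add 0.5 to each cell. Members near each region list were compared one-sided with 10000 random gene lists matched on length decile (a permutation of list membership within deciles), with adjustment over 200 tests. These lists draw on all protein-coding genes, including genes silent in microglia. The lists held 469 symbols, of which 465 matched. Mx1, Mx2, Meg3 and Trac did not. The list named myeloid transcription factors includes Jun, Fos and Klf genes, so its calls are not read as calls of myeloid identity.

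Named genes followed a rule: Mir137, Spi1 and Jdp2; per genotype the 10 genes with regions of that genotype only in the most antibodies; per antibody and genotype the 5 genes with the most regions; and up to 4 members per gene list, antibody and genotype. Other genes and regions named were chosen after their values were seen. Alternatives merged regions within 1 kb, counted base pairs, left out regions under 300 bp, took the upper part of each list by p, changed the gene-end window to 1 or 5 kb, used midpoints or all genes, assigned genes within 10 kb or by gene span, compared regions directly, took the genotype with more regions, or drew unmatched random lists. Others were added after the data were seen: regions with p under 0.05, regions named primary, and lists without multi-copy windows (1 Mb with at least 10 predicted genes) or without regions shared with another antibody.

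Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures from matplotlib 3.10.9. The functions were tested on simulated data. All 500 simulated regions got the nearest gene end that a direct search found. All 20 planted leaning lists of 20 members, 18 of them cWT (the rarer genotype among the 1806 H3K4me3 genes of 1 genotype), were recovered with 0 of 20 random lists called. A lean to the commoner genotype was not simulated. For H3K27ac cKO enrichment over 21887 genes, all 20 planted lists, with 12 of 25 members listed, were recovered and 0 of 20 random lists called. Weaker enrichment, such as the 5 of 26 myeloid transcription factors found in that list, was not simulated. Independent directions passed an unadjusted p of 0.05 in 12 of 200 simulated pairs. Both simulated antibodies were far less one-sided than most real ones, such as Ser5P with 4387 cKO and 50 cWT genes. The rate at the observed imbalance was not simulated.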

Results

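Microglia, the resident macrophages of the brain, were profiled by CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA beside the protein it binds. The mice carried a tamoxifen-inducible Cre at Tmem119, a gene used as a microglial marker, and either intact Mir137 (cWT) or Mir137 flanked by loxP sites (cKO). Mir137 encodes the microRNA miR-137. The labels give 30 samples in 10 groups, 3 replicates for each of 2 genotypes and 5 antibodies. The antibodies were against H3K27ac (a mark of active enhancers and promoters), H3K4me3 (a mark of active promoters), Pu.1 (a myeloid transcription factor), RNA polymerase II (Pol II) and Pol II phosphorylated at serine 5 of its tail (Pol II Ser5P, the form found near gene starts). About 100000 sorted cells were used per genotype, from mice 8 weeks old.

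The data analysed were 10 lists of genotype-specific regions, 1 per antibody and genotype, with 22399 regions in all, between 124 and 2166 bp wide. The lists hold no value per replicate, so no difference could be set against the spread between mice. Every test below compares lists of regions or genes, and its p-value describes those lists. Read depth is unknown. Of the 22399 regions, 169 had a deposited p-value under 0.05, and 18 had a deposited adjusted value under 0.05. The 4 lists of H3K4me3 (both genotypes), cWT Pu.1 and cWT Pol II held none of these 18. What the deposited p-values test is not known here, so they are not read as tests of a genotype difference.

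The first question was whether the targeted gene appeared. No listed region of any antibody lay within 10 kb of Mir137 (chromosome 3, 118433857 to 118433929). The nearest was an H3K4me3 region of the cKO list, 1074 kb away at 117359989 to 117360290. The lists therefore gave no reading of Mir137 in either genotype, and the genotypes are as labelled. Spi1, which encodes Pu.1, had an H3K27ac region in the cWT list inside the gene (chromosome 2, 91084363 to 91084677). A Pol II Ser5P region of the cKO list lay over the same position, at 91084333 to 91084715. Spi1 had 1 more Ser5P region in the cKO list, at 91096777 to 91097164, and 1 in the cWT list, at 91111854 to 91112163. Jdp2, which encodes a transcription factor of the AP-1 family, had 2 H3K27ac regions in the cWT list, at 85569632 to 85570381 and 85647894 to 85648447 of chromosome 12. Its Pol II region, at 85541073 to 85541547, and its 2 Ser5P regions, at 85541189 to 85541549 and 85612389 to 85612879, were in the cKO lists. Only the last of these lay within the Jdp2 gene span.

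**Figure D1:**
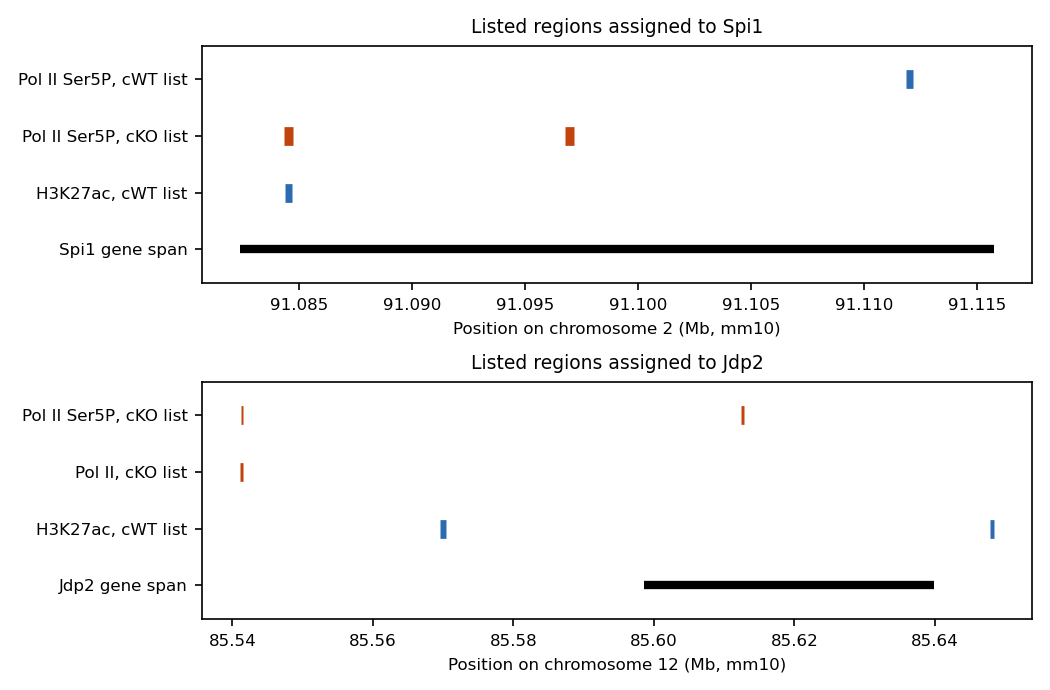
Listed regions assigned to Spi1 (upper panel) and Jdp2 (lower panel), with position in Mb on the horizontal axis and 1 line per list that held a region; red-brown blocks are cKO-specific, blue blocks cWT-specific, and the black bar is the gene span. In Spi1, an H3K27ac region of the cWT list and a Ser5P region of the cKO list lie at the same position, near 91084363.

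H3K27ac regions were mostly cWT-specific. Nek7, a kinase that takes part in NLRP3 inflammasome activation, led with 13 cWT-specific regions (gene at chromosome 1, 138483837 to 138619757). Med13l, a Mediator subunit, and Camk2d, a calcium-dependent kinase, had 10 each, Asap1 had 9 and Arhgap22 had 8. Of the 33 homeostatic microglia genes, 22 had H3K27ac regions in the cWT list only, 4 in both lists, and none in the cKO list only. Mef2c had 5 cWT-specific regions, Itgb5 had 4, and Gpr34 and P2ry12 had 3 each. Mef2c, Entpd1, Selplg and Sall1 were the 4 with regions in both lists. In the cKO list the highest number per gene was 3 regions, as at Lrrk1, Zfp516 and Dip2b and the predicted genes Gm3500 and Gm46963.

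In numbers, 847 of 7842 H3K27ac regions were cKO-specific, 10.8% (95% exact Clopper-Pearson interval 10.1 to 11.5%, covering counting error only). The cWT list was 8.26 times as long. Among the 36 regions with a deposited p-value under 0.05 the imbalance was much smaller: 15 were cKO-specific, 41.7% (95% exact interval 25.5 to 59.2%). Of those with an adjusted value under 0.05, 5 were cKO-specific and 7 cWT-specific. Regions of the cWT list were also wider, with medians of 435 and 348 bp. The mean log2 width was 8.81 ± 0.54 (SD, 6995 regions) in cWT and 8.52 ± 0.45 (SD, 847 regions) in cKO. The two-sided permutation test of that difference gave an adjusted p of 1.25e-05, from the smallest p that 100000 permutations can give.

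Around H3K27ac regions of the cWT list, 5 gene lists had more members than length-matched random lists (one-sided permutation of list membership among all protein-coding genes, as in every such comparison below). These were homeostatic microglia (26 of 33 members against a random mean of 6.88), myeloid transcription factors (18 of 26 against 5.23), phagocytosis and lysosome (18 of 30 against 6.98), inflammatory cytokines and NF-kB (16 of 34 against 5.29) and immediate early and dissociation genes (9 of 20 against 2.48). Adjusted permutation p was 0.00125 for the first 4, from the smallest p that 10000 random lists can give (0.0001), and 0.00435 for the last. Examples were Ets1 and Cebpb with 4 regions each, Elmo1 with 7, Dock2 with 4, and Nlrp3 and Fosb with 3 each. The cytokine list did not pass with gene ends within 10 kb (adjusted permutation p = 0.118) or with gene spans (adjusted p = 0.624). The immediate early list did not pass under these settings either (0.062 and 0.583). In the cKO list, myeloid transcription factors (5 of 26 against 0.834; Klf2, Irf8, Smad3 and Fos among them) and inflammatory cytokines and NF-kB (5 of 34 against 0.868; Nfkb1, Tlr4, Nfkbia and Cd14 among them) passed, with adjusted permutation p of 0.0104 and 0.0119. With gene ends within 10 kb neither passed (adjusted permutation p = 0.0754 and 0.504), and with gene spans the cytokine list did not (0.583). The random lists were drawn from all protein-coding genes, including genes silent in microglia. These results therefore say where listed regions lay, not that a group differed between genotypes.

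**Figure D2:**
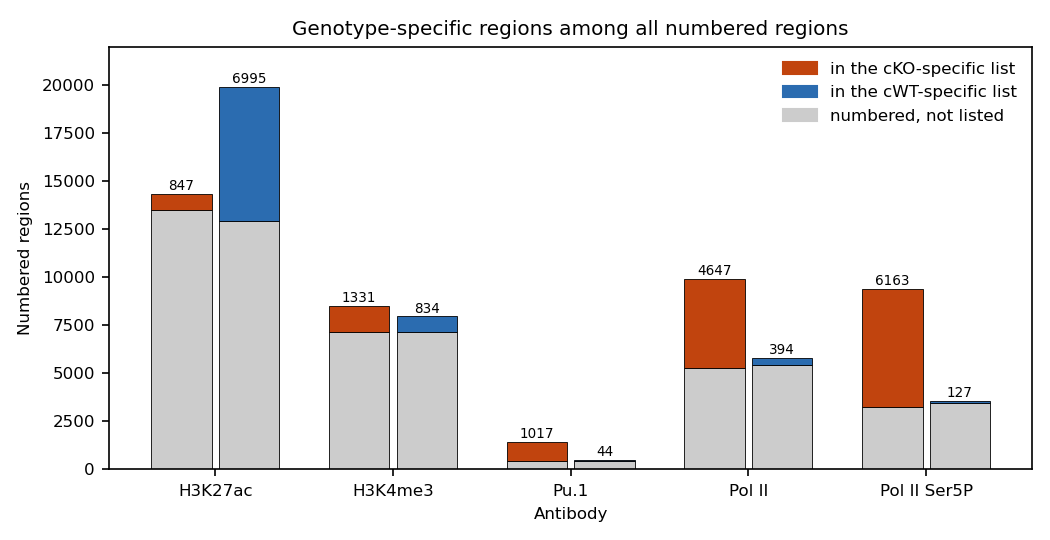
Number of regions (vertical axis) per antibody (horizontal axis), cKO at left and cWT at right of each pair; the coloured part is the genotype-specific list, whose size is printed above the bar, and the grey part is the remainder implied by the numbers in the region names. The coloured part is 6995 for cWT H3K27ac and 6163 for cKO Pol II Ser5P.

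Pol II regions were mostly cKO-specific. Irf2, an interferon regulatory factor, led with 8 cKO-specific regions (gene at chromosome 8, 46739745 to 46847458). Rcsd1 and Tns3 had 7 each, and Fgd2 and Chd7 (a chromatin remodeller) had 6 each. Of the homeostatic microglia genes, 16 had Pol II regions in the cKO list only, 2 in the cWT list only and 1 in both. Mef2c had 5 cKO-specific regions, Entpd1 had 4, Itgb5 had 3 and Mertk had 2. In all, 4647 of 5041 Pol II regions were cKO-specific, 92.2% (95% interval 91.4 to 92.9%). The cWT list, with 394 regions, was led by Gm52481 with 4, and 9530057J20Rik and Hivep2 with 3 each. Gm52481 lies on chromosome Y (90742729 to 90745083). Its 4 regions, between 90752002 and 90836740, all lay outside this span and were assigned to it by distance. Whether reads at Gm52481 and 9530057J20Rik come from other copies in the genome was not tested.

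Over all listed regions, Pol II Ser5P was the most one-sided, with 6163 of 6290 regions cKO-specific, 98.0% (95% interval 97.6 to 98.3%). Without regions under 300 bp, Pu.1 had the higher share (99.2 against 98.5%), with 95% exact intervals that overlap (97.9 to 99.8% and 98.1 to 98.8%). That Pu.1 share rests on 470 cKO and 4 cWT regions, since the cut lies above both Pu.1 median widths (291 and 221 bp). Eed (a Polycomb subunit), Ccny, Zmiz1 and Reep3 had 7 cKO-specific regions each, after Gm52481 with 9. Those 9 regions, between 90718796 and 90812088 of chromosome Y, were assigned to Gm52481 by distance and all lay outside its span. Of the 26 myeloid transcription factors, 16 had Ser5P regions in the cKO list only and 4 in both. The cKO regions included 4 each at Fos, Batf3 and Cebpb and 2 at Cebpa. Of the homeostatic microglia genes, 19 had cKO-specific regions and none had cWT-specific ones. Bin1 led with 6. In the cWT list of 127 regions, Gm52481 (all outside its span) and Mid1 had 3 each, and Jun, B4galt5 and Tmem267 had 2 each. Mid1 reaches into the pseudoautosomal region shared by X and Y.

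Both polymerase lists of cKO passed the comparison with random lists for the same 5 groups: homeostatic microglia (17 of 33 members for Pol II and 19 of 33 for Ser5P), myeloid transcription factors (17 and 20 of 26), inflammatory cytokines and NF-kB (15 and 20 of 34), phagocytosis and lysosome (13 and 17 of 30) and immediate early and dissociation genes (11 and 13 of 20). Adjusted permutation p lay between 0.00125 and 0.0119. Ccl2 and Il10ra had 3 Pol II regions each, and Socs3 and Tnfaip3 had 3 Ser5P regions each. Ribosomal proteins passed for both (8 and 15 of 30, adjusted permutation p = 0.0369 and 0.00125). Argonaute and nuclear microRNA machinery passed for Pol II (8 of 14, with Dgcr8 and Ago2 at 2 regions each, adjusted permutation p = 0.037), and transcription machinery for Ser5P (15 of 31, with Cdk9 at 3 regions, adjusted p = 0.0179). The homeostatic call for Ser5P did not pass with gene ends within 10 kb (adjusted permutation p = 0.139). The argonaute call did not pass there either (adjusted permutation p = 0.0735). The immediate early call for Pol II did not pass with gene spans (adjusted permutation p = 0.333), nor did the ribosomal call for Pol II against unmatched lists (adjusted p = 0.349). The cWT Ser5P list passed for myeloid transcription factors (4 of 26: Jun, Spi1, Runx1 and Klf6, adjusted permutation p = 0.00125) and immediate early genes (2 of 20: Hspa1a and Btg2, adjusted p = 0.0239). The cWT Pol II list passed for none of the 20 lists.

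**Figure D3:**
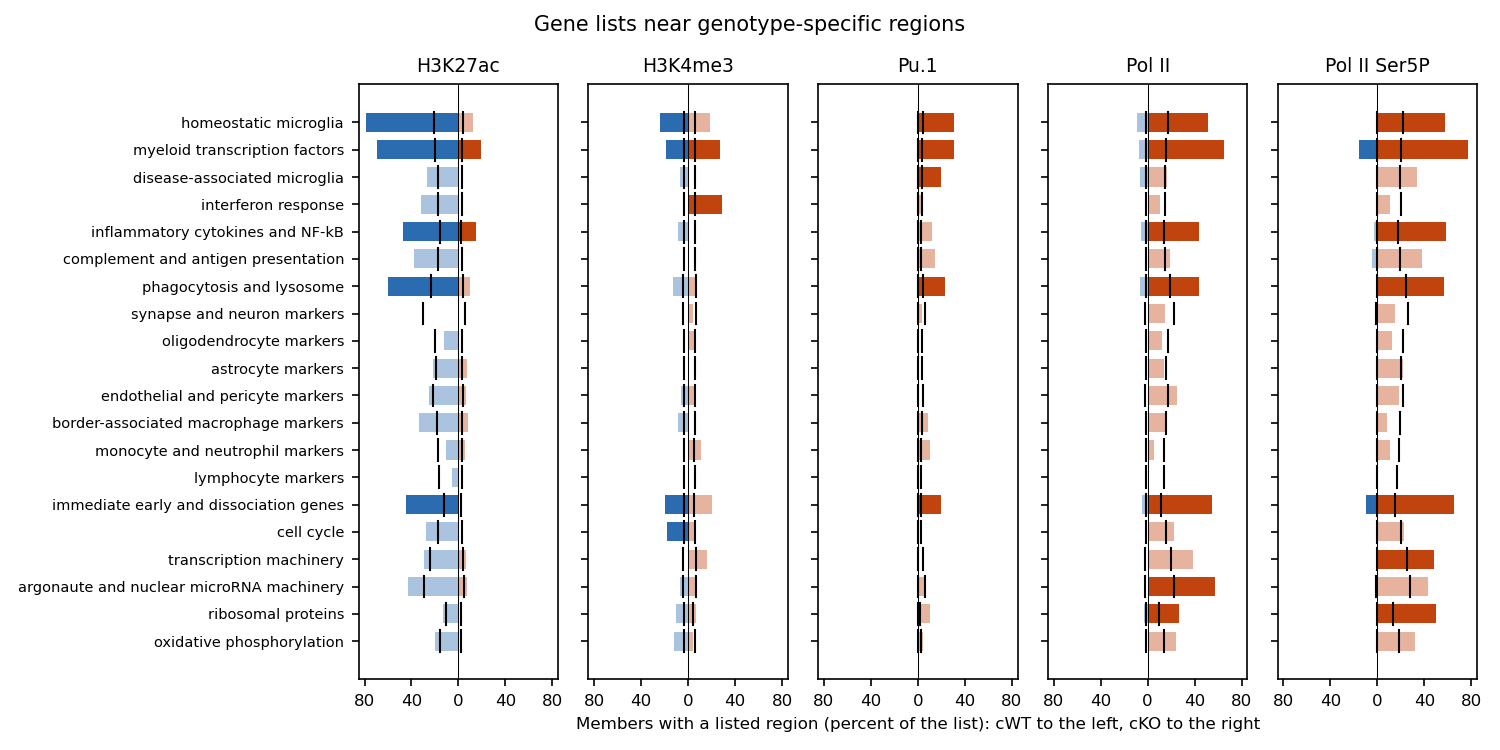
Share of each gene list's members (percent, horizontal axis) assigned to a listed region, for the 20 lists (rows) and 5 antibodies (panels), with cWT lists to the left and cKO lists to the right; black ticks are the mean of 10000 length-matched random lists, and dark bars passed an adjusted p of 0.05. In the homeostatic row the dark bars point left for H3K27ac and H3K4me3 and right for Pu.1, Pol II and Pol II Ser5P.

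Pu.1 regions were nearly all cKO-specific, 1017 of 1061, 95.9% (95% interval 94.5 to 97.0%). Pip4k2a and Ninj2 had 4 cKO-specific regions each, as did the predicted gene Gm15319. Trib1, a pseudokinase involved in C/EBP turnover, had 3. Near cKO regions lay 10 of 33 homeostatic genes (Entpd1 with 2 regions, Bin1, Cst3 and Mef2a with 1 each), 8 of 26 myeloid transcription factors (Batf, Cebpa and Cebpb with 2 each), 7 of 30 phagocytosis and lysosome genes, 6 of 30 disease-associated microglia genes and 4 of 20 immediate early genes. Adjusted permutation p for these 5 lists lay between 0.00125 and 0.00917. The disease-associated call was lost with gene ends within 10 kb (adjusted permutation p = 0.133) and with gene spans (adjusted p = 1). The myeloid factor call was lost likewise (adjusted permutation p = 1 and 0.674), and the immediate early call with gene spans (adjusted p = 0.824). The cWT list held 44 regions and passed for no gene list. It held 1 region in Lars2 (chromosome 9, 123461875 to 123462178).

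Over all listed regions, H3K4me3 was the least one-sided, with 1331 of 2165 regions cKO-specific, 61.5% (95% interval 59.4 to 63.5%). Among the few regions with p under 0.05 the order is not settled. There H3K27ac had 41.7% cKO-specific regions (15 of 36) and H3K4me3 62.5% (10 of 16). The 95% exact intervals, 25.5 to 59.2% and 35.4 to 84.8%, overlap and both include 50%. Of the 28 interferon response genes, 8 had a region in the cKO list and none in the cWT list. These included Ddx58 (a sensor of viral RNA, region at chromosome 4, 40239053 to 40239714), Xaf1, Irf1 and Oas1a, with 1 region each. This list passed against random lists (random mean 1.61, adjusted permutation p = 0.00435). Its lean towards cKO against the other H3K4me3 genes had a raw two-sided Fisher's exact p of 0.0284 and an adjusted p of 1. All 8 tested members were already cKO-only, so no smaller p towards cKO was possible. In H3K27ac, where most regions were cWT-specific, 9 interferon members were cWT-only and none cKO-only, Ddx58 and Xaf1 among the 9. The cKO lists of Pol II and Ser5P held 3 of 28 members each, against random means of 4.21 and 5.58. Homeostatic genes had H3K4me3 regions in cWT only for 8 members (Entpd1, Fcrls and Ltc4s among them) and in cKO only for 6 (Siglech, Itgam, Mef2c and P2ry12 among them). The cWT set passed against random lists (adjusted permutation p = 0.00125); the cKO list held 6 members against a random mean of 1.99 (adjusted permutation p = 0.0724). Myeloid transcription factors passed in both lists (7 members in cKO and 5 in cWT, adjusted permutation p = 0.00381 and 0.015), immediate early genes in cWT (4 members, adjusted p = 0.022; the cKO list also held 4, adjusted p = 0.0724) and cell cycle in cWT (Plk1, Ccne1, Mcm3 and Aurkb, adjusted p = 0.0488). The cell cycle call did not pass with gene spans (adjusted permutation p = 0.0653).

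The next question was whether any gene group leaned to a genotype beyond the imbalance of its antibody. Of 45 tested pairs of gene list and antibody with at least 5 members, none passed (two-sided Fisher's exact test, Benjamini-Hochberg adjusted), and 1 had an unadjusted p under 0.05, the interferon list in H3K4me3. For the homeostatic genes in H3K27ac, 0 cKO-only and 22 cWT-only members stood against 323 and 3876 other genes (odds ratio 0.266, 95% interval 0.0161 to 4.40). With all members of a list in the genotype that already held most genes, none of the 39 pairs outside H3K4me3 would have reached an unadjusted p of 0.05 (smallest Fisher's exact p = 0.407), and 3 of the 6 in H3K4me3 would. The smallest Fisher's exact p of those 3 was 0.00161 (homeostatic list), which as the smallest of 45 would not pass Benjamini-Hochberg adjustment. The interferon list in H3K4me3, with all 8 tested members in cKO, already had the smallest p it could reach towards cKO. For the 39 pairs the test could therefore call only a lean to the rarer genotype. In H3K4me3 a lean to cKO could not pass on its own. The absence of calls therefore does not show that a group followed the other genes.

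At many genes H3K27ac regions were cWT-specific and polymerase regions cKO-specific. Of 1476 genes with regions of 1 genotype only in both antibodies, 1310 had H3K27ac in cWT and Pol II in cKO, and 90 had both in cKO. For Ser5P the first count was 1574 of 1717 genes. Among them was P2ry12, a purinergic receptor of homeostatic microglia (chromosome 3, 59216271 to 59262985). At the level of regions, 714 of 876 overlaps paired cWT H3K27ac with cKO Pol II (odds ratio 0.497, 95% interval 0.268 to 0.922, raw Fisher's exact p = 0.0517, adjusted p = 0.172). In Mef2c, which encodes a transcription factor, a cWT H3K27ac region at 83540164 to 83540697 of chromosome 13 overlapped cKO regions of Pol II (83540212 to 83540681) and Ser5P (83540147 to 83540712). Given each antibody's imbalance, the H3K27ac and Pol II directions of genes showed no association past the threshold (odds ratio 0.749, 95% interval 0.326 to 1.72, adjusted p = 0.699, two-sided Fisher's exact test).

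Of the 10 pairs of antibodies, only Pol II and Pol II Ser5P passed. For H3K27ac with Pu.1, all 26 genes cKO in H3K27ac were also cKO in Pu.1. No stronger agreement was possible there, so that pair could not pass towards agreement. Whether the other pairs could have passed was not tested, so the absence of a call does not show independent directions. The counts of the pair that passed follow. Of 2334 genes, 2190 were cKO in both and 7 cWT in both, with 11 and 126 opposed (odds ratio 11.3, 95% interval 4.42 to 28.8, adjusted p = 3.13e-04, two-sided Fisher's exact test). With gene ends within 10 kb this pair did not pass (odds ratio 3.62, adjusted Fisher's exact p = 0.519), while under the other alternatives adjusted p lay between 7.97e-09 and 0.0329. Pu.1 and Ser5P had an unadjusted Fisher's exact p of 0.0239 (449 genes cKO in both, adjusted p = 0.119). The labels give the same catalogue number for the H3K27ac, Pol II and Ser5P antibodies. The H3K27ac lists differed from both polymerase antibodies in cKO share (10.8% against 92.2 and 98.0%) and lay less often near gene ends (33.6 and 30.9% in cKO and cWT, against 51.1 and 42.4% for Pol II and 54.4 and 52.8% for Ser5P). Whether the Pol II and Ser5P lists come from separate antibodies was not tested.

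Across antibodies, Ninj2, Uvrag (an autophagy regulator), Anxa3, Hk2 (a hexokinase of glycolysis), Fli1 and Batf (transcription factors) were cKO-only in 4 antibodies each. In the fifth antibody, H3K27ac, 4 of them had cWT regions: 7 at Anxa3, 4 at Uvrag, 3 at Hk2 and 1 at Batf. Ninj2 and Fli1 had no region in the H3K4me3 lists. The predicted genes Gm3667 (with 1 cWT H3K27ac region), Gm3696 and Gm38664 were cKO-only in 4 antibodies as well, and Gm7876 in 5. In all, 45 genes were cKO-only in 4 antibodies and 1 in 5, and the genes named were those with the most regions among ties. Most Pu.1, Pol II and Ser5P regions were cKO-specific, and how many such genes list lengths alone would give was not tested. Whether reads at the predicted genes come from other copies was not tested. For Fli1, the 3 cKO regions of Pol II (32508645 to 32509131), Ser5P (32508602 to 32509177) and Pu.1 (32508645 to 32509108) on chromosome 9 overlapped. In the cWT lists Pmepa1, Slc16a14, Zfp213, Mid1, Ywhaz, Cradd, Gm40035, Ltc4s and Cdh23 were cWT-only in 3 antibodies, and Duxf3 in 4. They were named in the same way from 15 genes cWT-only in 3 antibodies and 1 in 4. Of the 10 named, all but Zfp213 also had cKO regions in another antibody. Pmepa1, with 5 cWT H3K27ac regions, had 3 cKO Ser5P regions, and Cradd had 5 cKO Pol II regions.

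Markers of other cell types were counted in the same way. No synapse and neuron gene of 27 had an H3K27ac region (random mean 8.26 for the cWT list), and 4 had a Ser5P region in the cKO list (Cacna1a, Dlg4, Grin2b and Camk2a). Oligodendrocyte markers had 2 of 16 members in the cWT H3K27ac list (random mean 3.16) and 2 in the cKO Ser5P list, with Mbp at 3 and 2 regions. Among astrocyte markers, Slc1a3, a glutamate transporter, had 7 H3K27ac regions in the cWT list, 1 in the cKO list, and 6 Ser5P regions in the cKO list. In the cWT H3K27ac list astrocyte markers had 3 of 14 members against a random mean of 2.71, endothelial and pericyte markers 4 of 16 against 3.53 (Pecam1 with 3 regions), border-associated macrophage markers 4 of 12 against 2.17, monocyte and neutrophil markers 2 of 19 against 3.25 (Ccr2 with 3 regions) and lymphocyte markers 1 of 17 against 2.77 (Ncr1). Complement and antigen presentation had 8 of 21 members there against 3.65 (Cd86 with 3 regions), and oxidative phosphorylation 5 of 25 against 4.00. None of these lists passed against random lists in any antibody and genotype; fewer members than random was not tested.

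Position relative to genes differed for 1 antibody. Pol II regions lay within 2 kb of a protein-coding gene end in 51.1% of the cKO list (2375 of 4647) and 42.4% of the cWT list (167 of 394), a difference of 8.72 percentage points (adjusted p = 0.00467, two-sided Fisher's exact test). For Pu.1 the shares were 32.6 and 15.9% (adjusted Fisher's exact p = 0.0505). The difference passed within 5 kb (adjusted Fisher's exact p = 0.00811) and with all annotated genes (0.0232), and not within 1 kb (0.143). For H3K27ac (33.6 and 30.9%), H3K4me3 (74.8 and 75.9%) and Ser5P (54.4 and 52.8%) no difference passed. Median widths in the cKO and cWT lists were 291 and 221 bp for Pu.1, 353 and 313.5 bp for Pol II, and 369 and 307 bp for Ser5P, each with an adjusted permutation p of 1.25e-05. H3K4me3 medians were 380 and 394 bp (adjusted permutation p = 0.169). The share of regions on chromosome X did not differ past adjustment in any antibody. The closest was Pol II (2.07% in cKO and 3.85% in cWT, adjusted Fisher's exact p = 0.149).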

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

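All explanations and tests in this part were chosen after the results were seen. The cKO share of regions differed between antibodies. Against H3K27ac it was higher by 50.7 percentage points for H3K4me3, 85.1 for Pu.1, 81.4 for Pol II and 87.2 for Pol II Ser5P. Each stood out because a Fisher's exact test of the difference, over regions, gave a p below the smallest number the software can hold. Regions are not replicates, so this describes the lists.

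More reads or material in every cKO library would lengthen all cKO lists, and the H3K27ac share of 10.8% argues against it as the cause of the whole pattern. The remainders left by the numbers in the region names differ between the genotypes by at most 5.61%, so the lists may hold regions called in 1 genotype and not in the other, more than tested differences in signal. Depth or enrichment that differed separately for each antibody stays open, since the longer list held the wider regions in the 4 most one-sided antibodies, but not in H3K4me3 (medians of 380 bp in the longer list and 394 bp in the shorter, adjusted permutation p = 0.169). Real changes in occupancy could give the same widths. An effect of the Mir137 deletion on particular gene groups cannot be told apart from none (smallest adjusted Fisher's exact p = 1). Outside H3K4me3 the test had no power for a lean to the genotype that held most genes. In H3K4me3 the smallest Fisher's exact p possible for such a lean was 0.00161, which alone would not pass adjustment over 45 pairs.

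Immunoglobulin V segments are outside the gene comparisons, which used protein-coding genes. The H3K27ac cKO list held 11 regions within 2 kb of a V segment and the longer cWT list held 2. No test is given, because neighbouring regions are not independent. Of the 11, 10 lay on chromosome 12 between 115067926 and 115692454, and 9 were numbered consecutively. The cause was not tested.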

How the results depend on the processing

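Values under alternatives were counted, with predicted-gene shares left out. Of these, 61 kept direction and side of the threshold or stayed within the interval or 1.5 times the count. Another 19 moved, 3 became stronger, 1 became weaker and none reversed. The stronger ones are the Pu.1 gene-end difference within 5 kb and with all annotated genes, which newly passed, and the number of antibody pairs with associated directions. The weaker one is that number under another setting. The alternatives by p-value, the word primary, multi-copy windows and shared regions were chosen after seeing the data. No paired analysis was possible because the lists hold no value per replicate; for the same reason no replicate could be left out in turn. The Pu.1 motif and miR-137 seed searches and their alternatives were not run, since no genome sequence was used. Taking the upper part of each list by p, counted among the 61, keeps the share by construction and tests nothing. The leaning gene lists, also among the 61, had limited power. Unknown depth limits every share.

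In the settings below the cKO share lay outside the counting interval of the full lists. By base pairs it was 8.84% for H3K27ac, 97.0% for Pu.1, 93.1% for Pol II and 98.3% for Ser5P. Without regions under 300 bp it was 9.06, 99.2, 93.6 and 98.5% in the same order, with 4 cWT regions left for Pu.1. With p under 0.05 it was 41.7, 81.8, 89.5 and 89.7%, from few regions (36 of 7842 for H3K27ac); the exact intervals for H3K27ac (25.5 to 59.2%) and Pu.1 (48.2 to 97.7%) include 50%. With regions named primary it was 14.3, 91.8, 94.4 and 96.5%, and 66.7% for H3K4me3. Without regions shared with another antibody it was 9.76% for H3K27ac and 97.5% for Ser5P. For regions named primary, the exact interval of each antibody includes the share of its full lists. For H3K4me3 it runs from 34.9 to 90.1% (8 of 12 regions). With p under 0.05 the intervals of Pu.1 and Pol II include the full share, and those of H3K27ac and Ser5P do not. The shifts by base pairs and without regions under 300 bp follow from the wider regions of the longer lists. Causes of the other shifts were not tested.

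The Pu.1 gene-end difference passed within 5 kb (23.2 percentage points) and with all annotated genes (21.1 points). The number of antibody pairs with associated directions, 1, became 0 with gene ends within 10 kb and 3 with gene spans, which added Pu.1 with Pol II and with Ser5P. The cause was not tested. Leaning gene lists stayed at 0 of 40 to 46 pairs, with limited power. Enriched lists numbered 34, and 27 to 35 under the alternatives, with 26 of the 34 shared at 10 kb and 26 with gene spans.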

Other observations

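All tests in this part were chosen after the data were seen. Of 12 gene families defined by symbol, none of 36 leaning tests passed (2 unadjusted, Fisher's exact test; whether they could have passed was not tested), and 7 of 120 comparisons with random lists passed. Histone genes passed in 5 lists: 16 of 101 members near cWT H3K27ac regions (adjusted permutation p = 0.0024), 16 near cKO Ser5P, 15 near cKO Pol II, 11 near cKO H3K4me3 and 6 near cWT H3K4me3 (adjusted p = 0.0309). Histone genes lie in clusters, so members are not independent. Zfp zinc finger genes had 55 of 397 members near cKO H3K4me3 regions against a random mean of 25.3 (adjusted permutation p = 0.0024). Their lean to cKO had a raw Fisher's exact p of 0.00513 and an adjusted p of 0.185. Proteasome genes had 19 of 51 members near cWT H3K27ac regions against 8.93 (adjusted permutation p = 0.01).

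On the Y chromosome below 90 Mb, Eif2s3y and Ddx3y had H3K4me3 and Ser5P regions in the cKO lists, and Ddx3y and Uty had Pol II regions there. No cWT list held a region at these 3 genes. Of all listed regions, 61.5% of H3K4me3, 92.2% of Pol II and 98.0% of Ser5P ones were cKO-specific. So few Y regions in the cKO lists are therefore not read as a difference between the genotypes on Y. The cWT H3K4me3 numbering leaves 3 unlisted regions between its 2 listed regions of this part, so Y regions were called in cWT as well. Mitochondrial regions numbered 6 in cKO and 1 in cWT lists (Fisher's exact p = 0.268).

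Of the 18 regions with an adjusted value under 0.05, 11 coincided with a listed region of another antibody, against a mean of 6.1 in draws from the same lists (permutation p = 0.0117). The 11 include 2 pairs that coincide with each other, 1 near Tcp10c and 1 in Lars2. Counted once each, 9 of 16 sites coincided against a mean of 5.08 (permutation p = 0.0288), 7 of them with the opposite genotype against a mean of 2.12 (permutation p = 0.0022). The draws were made within each list, without matching on width or signal. Most of the 18 regions were wider than their list's median, such as 511 against 291 bp for 1 cKO Pu.1 region. Sites that collect fragments whatever the antibody are a candidate explanation, which the draws cannot tell apart from width or signal. A genotype effect shared by the antibodies would give the same genotype, and 72.7% of the 11 regions, or 77.8% of the 9 sites (95% exact interval 39.99 to 97.2%), had the opposite one, which does not decide.

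Predicted genes (symbols Gm or LOC with a number) took 7.53% of assigned cKO H3K27ac regions and 2.44% of cWT ones, and 3.03% of cKO and 7.97% of cWT Pol II regions. The shorter list had the higher share there and for Ser5P (224 of 5934 cKO and 8 of 123 cWT regions), but for H3K4me3 (5.39% in cKO and 3.81% in cWT) and Pu.1 (7.25 and 5.88%) the shorter list had the lower one. Reads placed among near-identical gene copies might raise the share in cKO H3K27ac. Without multi-copy windows its excess went from 5.09 to 2.36 percentage points (Fisher's exact p = 1.80e-04), so these windows carry part of it and the remainder stays open. Without them the difference (cKO minus cWT) went from -4.93 to -3.12 points for Pol II (Fisher's exact p = 9.81e-04), from -2.73 to -3.58 for Ser5P, which then passed (adjusted Fisher's exact p = 0.0335), and from 1.37 to -2.20 for Pu.1, where the cWT share rests on 2 of 34 regions.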
